A study of Mus musculus with 10 samples.

How the data were processed

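RNA from 10 mouse cell cultures was extracted with Trizol, prepared with an Ambion whole-transcript kit and hybridised to Affymetrix gene arrays, per the labels' protocols. The deposited table holds 1 log2 intensity value per probe set and array for 35556 probe sets, and the submitters' processing notes name RMA and Partek without versions. RMA subtracts background, normalises between arrays and summarises probes, which compresses differences of dim probe sets and makes value distributions alike. The log base was read from the values, which ran from about 2 to under 15 with array medians near 8, since no file header states it. Array medians lay between 7.66 and 7.76. A genome build is not given in the sources used here, so no coordinates are reported. Scan dates and batches were not analysed here.

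Probe sets were named through the platform's annotation table: 21789 had 1 gene symbol, 1621 had several and 12146 had none here, and only those with 1 symbol were used. Of these, 21698 matched the mouse RefSeq gene table by gene number, and 0 symbols changed. For the 999 genes with more than 1 probe set, the one with the highest mean was kept, giving 19938 genes. No value was filtered or rescaled in the main analysis, and 0 pairs of arrays held identical values. The labels say the 2 samples of each group were biological replicates.

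One mean per group was fitted over all 10 arrays with limma 3.58.1 in R 4.3.3, so that the 5 groups share an estimate of the spread (5 residual and 4.9 prior degrees of freedom; median SE of a difference 0.13). P-values were adjusted per comparison by the Benjamini-Hochberg method over all genes, with 0.05 as threshold, and fold size was used only to count genes past 2-fold. There were 34 gene lists with 695 entries, 643 of them measured, fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation. With an estimated correlation camera also uses only the 5 residual degrees of freedom, which makes it stricter. A lost call therefore does not by itself show correlation among the genes of a list. Counts "adjusted over the list alone" adjust p within the list's measured genes. Some entries were not analysed here. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots.

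The genes named were picked by a rule set before the data were examined. It took the 10 largest rises and 10 largest falls per comparison (5 and 5 for CNS_NSC against ESC) among called genes with separated replicates, a higher mean at or above the median gene (8.10) and no predicted name. It added up to 2 rising and 2 falling called members of each list, or the member with the largest difference where none was called, and a set of landmark genes. The text names a part of these. Genes outside the rule are said to be chosen after their values were seen.

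The fit was tested on simulated data: arrays were drawn for 19938 genes from the fitted group means and residual spread, with pNSC_L set equal to ESC except for genes changed by known amounts. Of the genes changed by a log2 difference of 0.5, 17.9% were called, against 71.6% at 1 and 98.5% at 2, and 4.4% of calls were false. The simulation gave 135 calls, fewer than any comparison below, so its adjusted threshold was stricter. It also gave every group the same spread, while the replicate differences had an SD of 0.31 in pNSC_L and 0.15 in dNSC. These rates therefore check the fit and do not carry over to the comparisons below. Alternatives were 2 further normalizations, 2 filters on dim genes, other variance models, array weights, only the 2 groups compared, the replicate number as a block, the mean of all probe sets of a gene, and leaving out each replicate in turn.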

Results

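The arrays compared 5 kinds of mouse cell that span the passage from embryonic stem (ES) cells to neural stem cells in culture. ESC were, per the labels, cells of the R1 line, a male mouse ES line, grown on mitotically inactive fibroblast feeders in 15% serum with Lif at 1000 U/ml, the cytokine that holds mouse ES cells undifferentiated. pNSC_L were primitive neural stem cell spheres formed directly from ES cells in serum-free medium with Lif, and pNSC_LF were such cells passaged with Lif, 10 ng/ml FGF and heparin. dNSC were definitive neural stem cells derived from primitive ones in 20 ng/ml FGF and 20 ng/ml EGF with heparin and the supplement B27, without Lif. CNS_NSC were neural stem cells grown in the same amounts of FGF, EGF and heparin, with no B27 stated, from the forebrain of E11.5 mice of the ICR strain. Each group had 2 biological replicates, 1 array each, and 19938 genes were analysed. Differences are on the log2 scale, first group minus second, ± SE from limma with n = 2 arrays per group, and a gene or gene list is said to rise or fall where limma or camera gave it an adjusted p below 0.05. The small number of arrays limits the precision of every value.

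Replicates correlated at r = 0.9972 in dNSC, 0.9962 in pNSC_LF, 0.9955 in ESC, 0.9887 in pNSC_L and 0.9885 in CNS_NSC across genes, which are not independent replicates. The replicates of pNSC_L differed by at least 2-fold at 167 genes and those of CNS_NSC at 277, against 30 in ESC, 23 in pNSC_LF and 1 in dNSC. The lower quartile of probe sets lay between 6.39 and 6.49 on the arrays, and the size of a difference from a group mean below it is uncertain. This holds for Dcn and Mmp3 against ESC, Dcn, Zdbf2 and Xist between dNSC and CNS_NSC, Dcx and Ptprz1 in the steps to dNSC and pNSC_LF, and Ptprz1, Gpm6a and Nr0b1 between CNS_NSC and ESC.

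**Figure D1:**
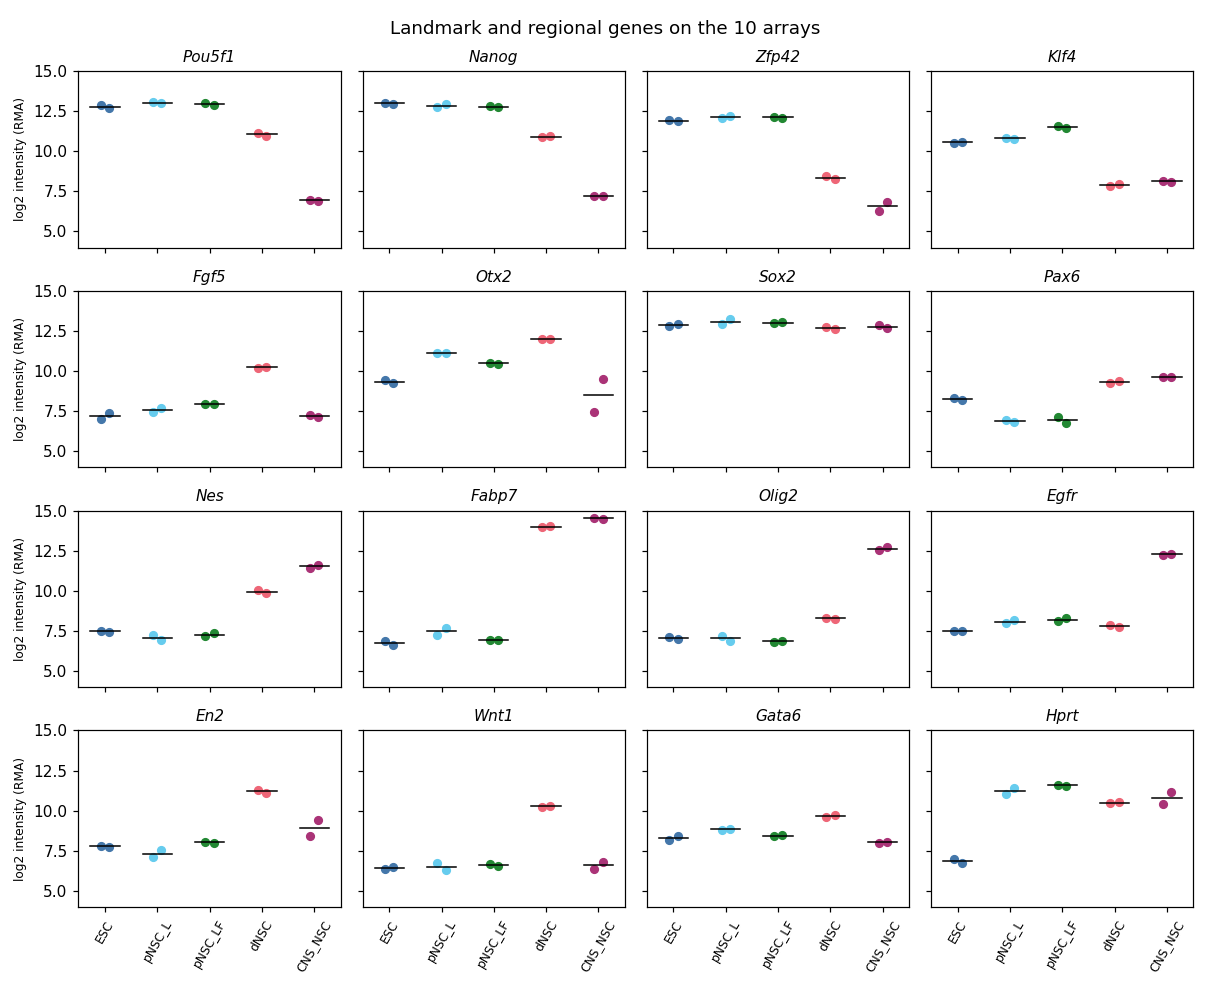
Log2 intensity (vertical axis) of 16 landmark and regional genes on each of the 10 arrays, by group (horizontal axis); points are single arrays and bars are group means of 2 arrays. Fabp7 was 7.04 higher in dNSC than in pNSC_LF, Zfp42 was lower by a log2 difference of -3.76, and Hprt was low in ESC alone among the 5 groups.

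The first comparison, pNSC_L against ESC, asked what changes when ES cells form spheres without serum and feeders. Genes of glycolysis and the hypoxia response fell as a group: 14 of 22 fell and none rose, and adjusted over the list alone 20 fell and 1 rose. The list had adjusted p = 2.6e-13, or adjusted p = 0.053 with an estimated correlation. Bnip3, a mitophagy receptor induced by low oxygen, fell by 3.15 ± 0.23, and the oxygen-sensing prolyl hydroxylase Egln3 fell by 2.01 ± 0.18. Dcn, the matrix proteoglycan decorin, rose by 3.33 ± 0.40, with Bgn, its close relative biglycan, higher by 2.96 ± 0.16 and the matrix metalloproteinase Mmp3 by 3.03 ± 0.22. The largest rise belonged to Hprt, a purine salvage enzyme, at 20.6-fold (4.37 ± 0.21, adjusted p = 5.5e-06 by limma), which read 6.99 and 6.76 on the ESC arrays and at least 10.45 on all 8 others. A difference of cell line beside that of culture is therefore not excluded in any comparison with ESC. The largest fall among genes that met the naming rule belonged to the ubiquitin ligase Mid1, at -3.62 ± 0.17.

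Of the 25 measured naive pluripotency genes, 5 rose, 3 fell and 17 did not pass the test; adjusted over the list alone, 7 rose and 5 fell. Their median difference was 0.11 and the list was not called (adjusted p = 0.25). Pou5f1, the core pluripotency factor Oct4, differed by 0.25 ± 0.11 (adjusted p = 0.20), Nanog by -0.16 ± 0.10 (adjusted p = 0.41) and Zfp42 by 0.23 ± 0.16 (adjusted p = 0.45). Tbx3 rose by 1.01 ± 0.10 and Tfcp2l1 by 0.72 ± 0.10, both transcription factors of the naive state, while Dppa3, a maternal factor also known as Stella, fell by 1.19 ± 0.24. The Dppa3 call was lost without ESC replicate 1 (-0.98, adjusted p = 0.093) or pNSC_L replicate 1 (-1.08, adjusted p = 0.057), and with an unmoderated test (adjusted p = 0.092).

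The S phase and replication list fell, with 8 of 22 genes lower and none higher (adjusted over the list alone, 10 and 0), and cyclin E2, Ccne2, differed by -1.32 ± 0.13. The list had adjusted p = 1.1e-05, or adjusted p = 0.22 with an estimated correlation. Of 20 G2-M genes 4 fell and none rose (adjusted over the list alone, 8 fell; adjusted p = 7.7e-05, or adjusted p = 0.49 with an estimated correlation). Of 20 germline and two-cell-like genes 7 fell and none rose (adjusted over the list alone, 10 and 1), among them the meiotic protein gene Hormad1 at -1.61 ± 0.21. That list had adjusted p = 1.1e-05, or adjusted p = 0.12 with an estimated correlation. Among 19 FGF-ERK targets 5 fell and none rose, over all genes and adjusted over the list alone (adjusted p = 0.0086, or adjusted p = 0.49 with an estimated correlation). The ETS factor Etv4 stood at -2.14 ± 0.14 and Id1, an inhibitor of helix-loop-helix factors, at -1.52 ± 0.19. Of 29 neuronal differentiation genes 7 fell and 1 rose (adjusted over the list alone, 7 and 2; adjusted p = 0.028, or adjusted p = 0.22 with an estimated correlation). They included the proneural factor Neurod1 at -2.43 ± 0.20 and the neurofilament gene Ina at -2.36 ± 0.18. Pax6, a neural and eye transcription factor, fell by 1.40 ± 0.12.

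Feeder fibroblast genes rose, 9 of 25 with 2 lower (adjusted over the list alone, 10 and 3; adjusted p = 7.5e-04, or adjusted p = 0.22 with an estimated correlation). Among them were Dcn and the chemokine gene Ccl2 (1.38 ± 0.21). Primitive and visceral endoderm genes rose, 7 of 26 with 3 lower (adjusted over the list alone, 8 and 3; adjusted p = 0.034, or adjusted p = 0.57 with an estimated correlation). The basement membrane collagen Col4a1 rose by 1.15 ± 0.10. Of 28 neural stem and progenitor genes 7 rose and 1 fell (adjusted over the list alone, 7 and 1), but the list was not called (adjusted p = 0.092). None of the 8 lists called here held with an estimated correlation, a test limited to 5 residual degrees of freedom. The neuronal list lost its call although its estimated correlation, -0.015, lay below the preset 0.01. In all, limma called 2662 genes, 1308 higher and 1354 lower, of which 208 and 231 differed by at least 2-fold. The count was 1102 without ESC replicate 1, 1205 without ESC replicate 2, 1587 with an unmoderated test and 1480 with the other 3 groups left out. With the dimmer 50% of genes left out 5 lists were called, and the neuronal, germline, feeder fibroblast and FGF-ERK lists lost their calls (adjusted p up to 0.085, 0.15, 0.18 and 0.13 over all settings). The feeder fibroblast call was also lost with the dimmer 30% left out. Without pNSC_L replicate 2 the neuronal and FGF-ERK lists were not called, and the endoderm list was not called without ESC replicate 1 or pNSC_L replicate 1, or with the dimmer 30% of genes left out (adjusted p up to 0.20).

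The second comparison, pNSC_LF against pNSC_L, concerned passage in Lif with FGF and heparin, which differ together. It showed the fewest differences of the 7 comparisons, 355 genes, 220 higher and 135 lower, of which 73 and 27 differed by at least 2-fold. Dmgdh and Bhmt2, enzymes of choline and methionine metabolism, rose by 3.09 ± 0.14 and 2.52 ± 0.12. Tfap2a, a transcription factor of ectoderm and neural crest, rose by 2.16 ± 0.14, and Ptprz1, a receptor phosphatase of neural progenitors, by 1.66 ± 0.15. Mmp3 and Bgn differed by -2.38 ± 0.22 and -2.24 ± 0.16. Dcn was lower by -2.33 ± 0.40, but this call was lost without pNSC_LF replicate 1 (adjusted p = 0.16) or replicate 2 (adjusted p = 0.14). It was also lost with a trended prior, an unmoderated test and the other groups left out (adjusted p = 0.051, 0.19 and 0.10), and that of Mmp3 with an unmoderated test (adjusted p = 0.062).

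Wnt targets rose as a list, although only 2 of 13 genes passed over all genes (adjusted over the list alone, 5 rose and 0 fell; adjusted p = 6.0e-05, or adjusted p = 0.39 with an estimated correlation). Axin2, a feedback inhibitor of the Wnt pathway, rose by 1.55 ± 0.13. The p53 targets rose, 1 of 14 over all genes with none lower (adjusted over the list alone, 3 and 0; adjusted p = 0.0088, or adjusted p = 0.39 with an estimated correlation), but not without pNSC_L replicate 2 (adjusted p = 0.12). Of 25 feeder fibroblast genes 1 fell and none rose (adjusted over the list alone, 8 fell and 2 rose; adjusted p = 0.0031, or adjusted p = 0.39 with an estimated correlation). The feeder fibroblast call was lost with dim genes left out and without pNSC_L replicate 2 (adjusted p up to 0.17). Of 25 naive pluripotency genes 1 rose and none fell over all genes (adjusted over the list alone, 1 and 2), and the median was -0.11. The list was called lower (adjusted p = 0.046, or adjusted p = 0.48 with an estimated correlation), but not after quantile or cyclic loess normalization, with dim genes left out, or without pNSC_L replicate 2 or either pNSC_LF replicate (adjusted p up to 0.57). The 1 called member of the naive pluripotency list, Klf4, moved against the list, higher by 0.72 ± 0.10, and was no longer called without pNSC_LF replicate 1 (0.65, adjusted p = 0.13) or replicate 2 (0.78, adjusted p = 0.057), or with the other groups left out (adjusted p = 0.081). Pou5f1 differed by -0.07 ± 0.11 (adjusted p = 0.88) and Nanog by -0.08 ± 0.10 (adjusted p = 0.85). None of the 11 lists called held with an estimated correlation. The gene count was 48 without pNSC_LF replicate 1, 70 without pNSC_LF replicate 2, 826 without pNSC_L replicate 2. It was 89 with an unmoderated test, 208 with array weights and 99 with the other groups left out. The share of called genes that were higher, 62%, also hung on single arrays: it was 49.5% without pNSC_L replicate 1 and 73.2% without pNSC_L replicate 2. Of the genes picked by the naming rule, 14 of the 44 that were called stayed so without each replicate in turn. The list count was 3 without pNSC_L replicate 2, 4 without pNSC_LF replicate 1, 7 without pNSC_LF replicate 2, 6 after quantile normalization, and 5 and 3 with the dimmer 30% and 50% of genes left out.

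The third comparison, dNSC against pNSC_LF, covered the removal of Lif, the addition of EGF and, as stated, B27, and FGF at 20 instead of 10 ng/ml. These differ together with further culture, so their effects cannot be separated here. Neural genes rose and naive pluripotency genes fell. Fabp7, a fatty acid binding protein of radial glia, rose 132-fold (7.04 ± 0.15, adjusted p = 1.3e-08 by limma), the neural cadherin Cdh2 by 4.69 ± 0.12, Zic1 by 5.14 ± 0.20, and the neural progenitor filament Nes by 2.66 ± 0.14. Zfp42, a marker of naive ES cells also called Rex1, fell by 3.76 ± 0.16, and Klf4 and Tbx3 differed by -3.62 ± 0.10 and -3.68 ± 0.10. Pou5f1 and Nanog fell less far in log2 terms, by 1.89 ± 0.11 and 1.84 ± 0.10.

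Of the 25 naive pluripotency genes 23 fell and 1, the RNA-binding protein gene Lin28a, rose by 0.64 ± 0.10 (adjusted over the list alone, 24 fell and 1 rose; median -2.06; list adjusted p = 4.3e-17, or adjusted p = 0.016 with an estimated correlation). Of 28 neural stem and progenitor genes 21 rose and 2 fell (adjusted over the list alone, 22 and 2; adjusted p = 1.0e-11). The 2 that fell were Egfr, the EGF receptor, by 0.37 ± 0.11, and Sox2, shared by ES and neural stem cells, by 0.35 ± 0.12. Egfr was no longer called without pNSC_LF replicate 2 (-0.29, adjusted p = 0.17) or dNSC replicate 2 (-0.30, adjusted p = 0.17). Sox2 was no longer called without any 1 of the 4 replicates of these groups (differences from -0.28 to -0.41). Its call was also lost with an unmoderated test (adjusted p = 0.077) and with the replicate number as a block (adjusted p = 0.052). Of 18 primed epiblast genes 14 rose and 1 fell by either adjustment, over all genes or adjusted over the list alone (adjusted p = 1.3e-07), with Fgf5, a marker of the primed epiblast, at 2.29 ± 0.14 and the Wnt antagonist Dkk1 at 3.47 ± 0.12. Of 29 neuronal differentiation genes 20 rose and 2 fell, also by both adjustments including adjusted over the list alone (adjusted p = 2.1e-07), with doublecortin, Dcx, at 3.36 ± 0.55.

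Mid- and hindbrain regional genes rose, 14 of 18 with none lower by either adjustment, over all genes or adjusted over the list alone (adjusted p = 6.2e-09, or adjusted p = 0.10 with an estimated correlation). They included the homeobox gene Nkx2-9 at 3.85 ± 0.12 and the signalling ligand Wnt1 at 3.64 ± 0.16. Of 19 forebrain regional genes 10 rose and 1 fell (adjusted over the list alone, 11 and 1; adjusted p = 4.6e-04, or adjusted p = 0.11 with an estimated correlation), a call lost with the dimmer 50% of genes left out (adjusted p = 0.29). Otx1, a forebrain and midbrain homeobox gene, rose by 2.37 ± 0.13. The list named sonic hedgehog targets rose, 10 of 12 with 1 lower (adjusted over the list alone, 11 and 1, adjusted p = 1.9e-05 by camera). The pathway's inhibitor Hhip rose by 2.67 ± 0.24 and its transcription factor Gli3 by 2.45 ± 0.17. This list mixes targets with components of the pathway, such as the ligand Shh and Gli3. Its rise therefore does not by itself show that the pathway was active. Of 20 imprinted genes 12 rose and 4 fell (adjusted over the list alone, 12 and 5; adjusted p = 4.1e-04, or adjusted p = 0.056 with an estimated correlation). The growth factor gene Igf2 rose by 4.06 ± 0.11 and Nnat, a membrane protein gene of the developing brain, by 4.67 ± 0.21. LIF-STAT3 targets fell, 12 of 22 with 2 higher by either adjustment, over all genes or adjusted over the list alone (adjusted p = 2.1e-04, or adjusted p = 0.055 with an estimated correlation). Of 20 germline and two-cell-like genes 13 fell and none rose (adjusted over the list alone, 14 fell; adjusted p = 9.8e-06), with Dazl, a germ cell RNA-binding protein gene, at -2.70 ± 0.11. Of 20 cholesterol synthesis genes 13 fell and none rose by either adjustment, over all genes or adjusted over the list alone (adjusted p = 4.8e-04, or adjusted p = 0.35 with an estimated correlation). Feeder fibroblast genes rose in the same step, 13 of 25 with 1 lower (adjusted over the list alone, 15 and 2; adjusted p = 4.5e-05, or adjusted p = 0.055 with an estimated correlation). Primitive and visceral endoderm genes rose too, 15 of 26 with 1 lower (adjusted over the list alone, 15 and 2; adjusted p = 4.5e-05, or adjusted p = 0.18 with an estimated correlation). Limma called 7706 genes, 3848 higher and 3858 lower, of which 1379 and 1060 differed by at least 2-fold. Of 19 lists called, 6 held with an estimated correlation: naive pluripotency, primed epiblast, neural stem and progenitor, neuronal differentiation, germline and two-cell-like, and the mixed sonic hedgehog list.

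**Figure D2:**
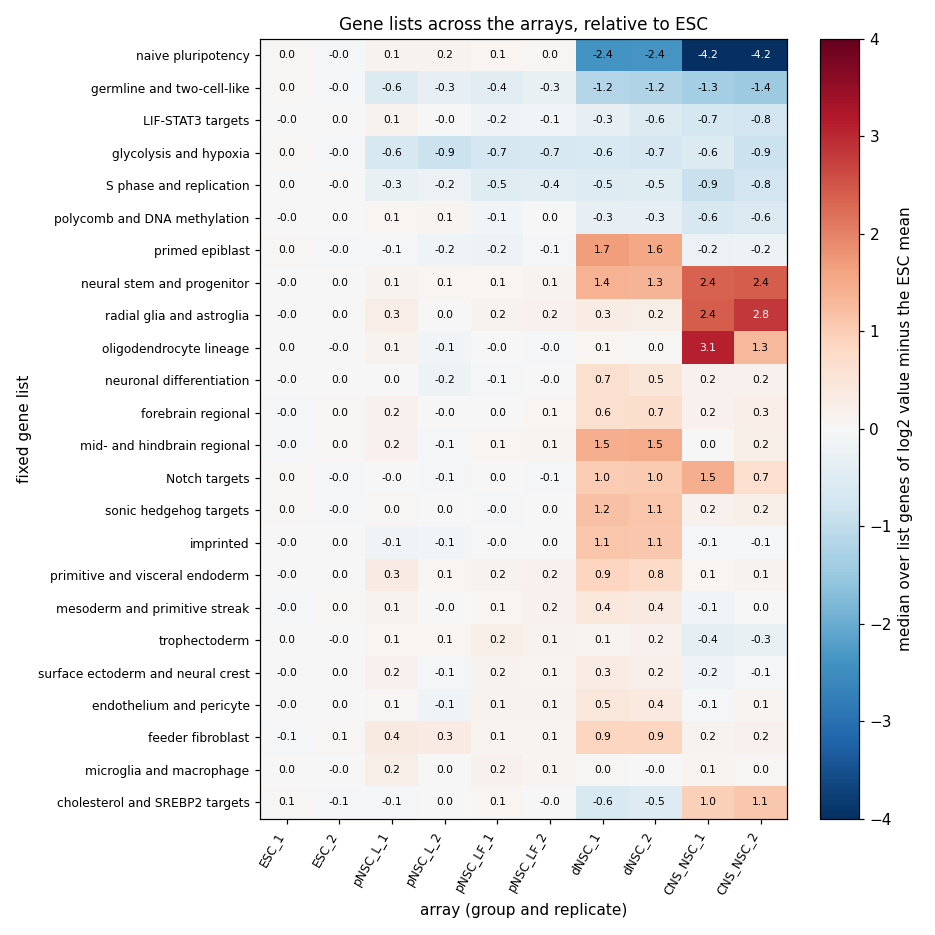
Median over the measured genes of 24 fixed lists (rows) of the log2 value minus the ESC mean, on each of the 10 arrays (columns), with red for higher and blue for lower than ESC. The naive pluripotency row falls in dNSC and further in CNS_NSC, where the median difference from ESC was -4.20.

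The fourth comparison set dNSC against CNS_NSC, the neural stem cells taken from the embryo. Genes of the naive pluripotency list were higher in dNSC: Pou5f1 by 4.10 ± 0.11 (17.2-fold, adjusted p = 8.5e-09 by limma), Nanog by 3.71 ± 0.10, and the ES cell chromatin factor Utf1 by 4.59 ± 0.16. This list also holds core pluripotency factors such as Pou5f1, so higher values do not by themselves show a naive state. Lower in dNSC were Olig1 at -5.64 ± 0.15 and Olig2 at -4.33 ± 0.13, transcription factors of neural progenitors and the oligodendrocyte lineage, the brain proteoglycan Bcan at -5.45 ± 0.16, the matrix protein tenascin C, Tnc, at -4.79 ± 0.22, and Egfr at -4.44 ± 0.11. Sox2 differed by -0.11 ± 0.12 (adjusted p = 0.57), Sox1 by 0.27 ± 0.13 (adjusted p = 0.13) and Pax6 by -0.32 ± 0.12 (adjusted p = 0.073, or 0.046 with the dimmer 50% of genes left out). Nes was lower in dNSC, by -1.58 ± 0.14.

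Of 25 naive pluripotency genes 20 were higher in dNSC and none lower (adjusted over the list alone, 21 and 0; adjusted p = 5.8e-15). Zfp42 was higher by 1.78 ± 0.16, while Klf4 differed by -0.22 ± 0.10 (adjusted p = 0.14, or 0.045 after quantile normalization). Of 18 primed epiblast genes 14 were higher and none lower (adjusted over the list alone, 14 and 1; adjusted p = 7.0e-09), with Fgf15 at 4.68 ± 0.12. Of 22 radial glia and astroglia genes 16 were lower and 1 higher (adjusted over the list alone, 18 and 1; adjusted p = 2.3e-10), and 16 of 20 imprinted genes were higher with none lower by either adjustment, over all genes or adjusted over the list alone (adjusted p = 3.0e-10), with Zdbf2 at 6.02 ± 0.17 and Igf2 at 4.07 ± 0.11. These 4 of the 21 lists called held with an estimated correlation. All 20 cholesterol and SREBP2 genes were lower by either adjustment, over all genes or adjusted over the list alone (adjusted p = 3.6e-14, or adjusted p = 0.076 with an estimated correlation). They included Insig1, a sterol-regulated brake on the pathway, at -2.46 ± 0.11 and Dhcr7, a late enzyme of cholesterol synthesis, at -2.20 ± 0.15.

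Of 28 neural stem and progenitor genes 16 were lower and 5 higher (adjusted over the list alone, 17 and 6; adjusted p = 1.7e-05, or adjusted p = 0.076 with an estimated correlation). Of 13 oligodendrocyte lineage genes 7 were lower and none higher (adjusted over the list alone, 8 lower; adjusted p = 1.7e-05, or adjusted p = 0.23 with an estimated correlation). The CNS_NSC replicates stood apart here: the median of the oligodendrocyte list relative to ESC was 3.12 and 1.29 on their arrays, against 0.09 and 0.04 in dNSC. Mid- and hindbrain genes were higher, 15 of 18 with 1 lower (adjusted over the list alone, 16 and 1; adjusted p = 9.3e-10, or adjusted p = 0.076 with an estimated correlation), led by Nkx2-9 at 3.95 ± 0.12 and Wnt1 at 3.65 ± 0.16. The forebrain regional list was not called (adjusted p = 0.12 by camera), with 8 of 19 genes higher and 3 lower (adjusted over the list alone, 9 and 3). CNS_NSC were taken from the forebrain, so the brain region differed along with the group. Of 26 primitive and visceral endoderm genes 18 were higher and 1 lower (adjusted over the list alone, 19 and 2; adjusted p = 3.8e-07, or adjusted p = 0.079 with an estimated correlation). Of 19 surface ectoderm and neural crest genes 12 were higher and none lower (adjusted over the list alone, 12 and 1; adjusted p = 4.9e-06, or adjusted p = 0.079 with an estimated correlation). Of 15 endothelium and pericyte genes 11 were higher and none lower (adjusted over the list alone, 12 and 0; adjusted p = 2.4e-06, or adjusted p = 0.076 with an estimated correlation). Of 25 mesoderm and primitive streak genes 13 were higher and none lower (adjusted over the list alone, 14 and 0; adjusted p = 4.1e-05, or adjusted p = 0.20 with an estimated correlation), a call lost with the dimmer 50% of genes left out (adjusted p = 0.066). Of 17 trophectoderm genes 8 were higher and none lower (adjusted over the list alone, 9 and 0; adjusted p = 7.6e-05, or adjusted p = 0.076 with an estimated correlation). Of 29 neuronal differentiation genes 13 were higher and 5 lower (adjusted over the list alone, 14 and 5; adjusted p = 0.014, or adjusted p = 0.076 with an estimated correlation). The neuronal call was lost with the dimmer 30% or 50% of genes left out and without CNS_NSC replicate 2 (adjusted p up to 0.94). Feeder fibroblast genes were higher, 15 of 25 with 3 lower by either adjustment, over all genes or adjusted over the list alone (adjusted p = 3.7e-04, or adjusted p = 0.076 with an estimated correlation), with Dcn at 3.19 ± 0.40. That list was not called with the dimmer 50% of genes left out (adjusted p = 0.096). Xist, the RNA that silences an X chromosome in female cells, was lower in dNSC by -6.28 ± 0.22, the Y-linked genes Eif2s3y and Uty were higher by 1.66 ± 0.21 and 2.26 ± 0.24, and the Y-linked gene Kdm5d was lower by -1.14 ± 0.20. Of the 7 genes on the list of Xist and Y-linked genes 3 were higher and 2 lower, over all genes and adjusted over the list alone. That list was not called (adjusted p = 0.93), and its median of -0.10 and mean of -0.30 differed in sign from its test, which pointed up. Limma called 6783 genes, 3501 higher and 3282 lower in dNSC, of which 1068 and 1003 differed by at least 2-fold. Mouse strain, the embryonic or ES cell origin, the brain region taken and, as stated, B27 differed along with the group, as did Xist. These and the sex of the cells therefore cannot be separated from it here.

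The last comparison with named genes, CNS_NSC against ESC, set the 2 control groups against each other. They differed at once in strain, origin, growth factors, Xist and, as stated, serum and feeders, whose effects cannot be separated here. Fabp7 was higher in CNS_NSC by 7.77 ± 0.15, Ptprz1 by 7.26 ± 0.15 and the neuronal membrane glycoprotein Gpm6a by 6.94 ± 0.18. Tdgf1, the pluripotency-associated co-receptor Cripto, was lower by -6.71 ± 0.12, the orphan receptor gene Nr0b1 by -6.80 ± 0.24 and Pou5f1 by -5.81 ± 0.11. All 25 naive pluripotency genes were lower by either adjustment, over all genes or adjusted over the list alone (adjusted p = 2.6e-24), and 25 of 28 neural stem and progenitor genes were higher with none lower, again also when adjusted over the list alone (adjusted p = 7.7e-15). Of 22 radial glia and astroglia genes 16 were higher and 1 lower (adjusted over the list alone, 18 and 1; adjusted p = 1.2e-08), and 17 of 20 germline and two-cell-like genes were lower with none higher by either adjustment, over all genes or adjusted over the list alone (adjusted p = 7.8e-09). These 4 of the 16 lists called held with an estimated correlation. Cholesterol and SREBP2 genes were higher in CNS_NSC, 17 of 20 with none lower (adjusted over the list alone, 20 and 0; adjusted p = 3.1e-07, or adjusted p = 0.20 with an estimated correlation). Of 22 glycolysis and hypoxia genes 16 were lower and 2 higher (adjusted over the list alone, 19 and 2; adjusted p = 6.7e-06, or adjusted p = 0.067 with an estimated correlation). Limma called 8736 genes, 4331 higher and 4405 lower, of which 1786 and 1531 differed by at least 2-fold. Set against the same CNS_NSC arrays, pNSC_L differed at 8701 genes and pNSC_LF at 8355, of which 3503 and 3300 differed by at least 2-fold.

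**Figure D3:**
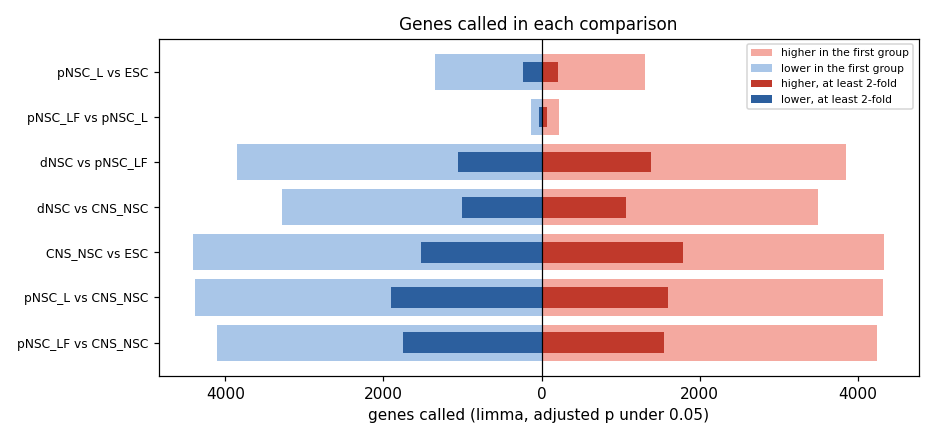
Number of genes called by limma (horizontal axis) in each of the 7 comparisons (rows), with genes higher in the first group to the right and lower to the left; pale bars count all called genes and dark bars those that differed by at least 2-fold. The count ran from 355 for pNSC_LF against pNSC_L to 8736 for CNS_NSC against ESC.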

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

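All the alternatives in this part were chosen before the data were examined, and the count of how the named genes fared was added after the results were seen.

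Requiring a 2-fold difference as well left 439 genes for pNSC_L against ESC, 100 for pNSC_LF against pNSC_L, 2439 for dNSC against pNSC_LF, 2071 for dNSC against CNS_NSC, 3317 for CNS_NSC against ESC, 3503 for pNSC_L against CNS_NSC and 3300 for pNSC_LF against CNS_NSC, a stricter rule by construction. With an estimated correlation, which also limits camera to the 5 residual degrees of freedom, 0, 0, 6, 4 and 4 lists were called in the first 5 of these. For pNSC_L against ESC the unmoderated test called 1587 genes and the fit of the 2 groups alone 1480, and 5 lists were called with the lowest 50% of genes left out. For pNSC_LF against pNSC_L these tests called 89 and 99 genes and array weights 208. In that comparison 6 lists were called after quantile normalization, and 5 and 3 with the lowest 30% and 50% of genes left out. No further cause was tested.

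Leaving out each replicate in turn leaves 1 array in a group, which is assumed to vary like the other groups. The range was 1102 to 3290 genes (6 to 9 lists) for pNSC_L against ESC and 48 to 826 genes (3 to 13 lists) for pNSC_LF against pNSC_L. It was 5706 to 5831 (18 to 19 lists) for dNSC against pNSC_LF, 4684 to 6173 (20 to 22) for dNSC against CNS_NSC and 7076 to 8163 (13 to 16) for CNS_NSC against ESC. It was 7885 to 8638 for pNSC_L and 6705 to 7773 for pNSC_LF against CNS_NSC.

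Of all called genes that the naming rule picked, in the order above, 59 of 90, 14 of 44, 111 of 127, 109 of 119 and 106 of 118 stayed called without each replicate in turn. Under every other alternative 61, 9, 113, 111 and 109 did, and 0 changed sign. With the replicate number as a block 2958, 407, 7943, 7108, 8992, 8982 and 8595 genes were called in the 7 comparisons, and Sox2 (dNSC against pNSC_LF) had adjusted p = 0.052. The replicate differences of same-numbered samples correlated at 0.138 to 0.375 in the 6 pairs of groups without dNSC and at -0.107 to 0.094 in the 4 pairs with dNSC. Since not every pair lay over 0.1, the numbers were not shown to pair the samples, and a pairing among the groups other than dNSC stays open.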

Other observations

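Every test in this part was chosen after the values it bears on had been seen.

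The probe sets annotated to the precursor genes of the miR-302 cluster, a microRNA family of pluripotent cells and chosen after their values were seen, were called higher in dNSC than in pNSC_LF and CNS_NSC. Mir302a read 7.05 and 7.42 in dNSC, Mir302b 6.61 and 6.81, Mir302c 7.35 and 7.57 and Mir302d 7.31 and 7.39, all under the median gene (8.10). On the other 8 arrays all 4 lay between 3.24 and 4.90, under the lower quartile of probe sets, so the size of the difference is not given. Mature microRNAs were not measured. Mid1, Ccdc141 and Dmgdh were picked by the naming rule. Mid1 had log2 values of 7.57 to 8.07 on the 4 pNSC_L and pNSC_LF arrays and of 10.23 to 11.41 on the other 6. Ccdc141 showed another order, 10.96 to 11.27 on those 4 arrays and 11.57 to 11.78 in CNS_NSC, against 8.06 to 8.15 in ESC and dNSC. Dmgdh stood at 10.36 and 10.37 in pNSC_LF and at most 7.40 elsewhere.

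Zinc finger genes Zfp640, Zfp980 and Zfp600, all picked by the naming rule, were called higher in dNSC than in CNS_NSC. They read 9.95 and 9.92, 10.24 and 10.20, and 8.66 and 8.19 in dNSC. On the ESC, pNSC_L and pNSC_LF arrays they read higher still, at 11.85 to 12.62, 11.47 to 12.13 and 9.30 to 10.08, so high values were not particular to dNSC. In CNS_NSC they read 4.54 and 4.07, 5.36 and 4.62, and 3.06 and 3.76, under the lower quartile of probe sets, so the size of the difference is not given. Xist read 12.75 and 12.03 in CNS_NSC and 5.97 to 6.97 on the other 8 arrays, and Eif2s3y 9.04 and 9.75 in CNS_NSC and 10.65 to 11.39 elsewhere. Kdm5d ran the other way, at 7.94 and 8.57 in CNS_NSC and 6.01 to 7.21 elsewhere. With Xist and the Y-linked Eif2s3y both above the median gene (8.10) in CNS_NSC, these values do not show cells of a single sex there. The CNS_NSC replicates differed in Otx2 (7.43 and 9.53) and, chosen after their values were seen, Ndrg2 (12.06 and 10.08) and Ugt8a (9.10 and 7.13).

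Hprt had a mean of 6.87 ± 0.16 (SD, n = 2) in ESC and values of 10.45 to 11.60 on the other 8 arrays. Over 3 scalings the smallest difference between pNSC_L and ESC was 4.33. Rescaling arrays that were already alike could not move 1 gene this far, so this does not test normalization. Among protein-coding X-linked genes with a mean at or above the median gene, the 10 nearest had a median difference of -0.10. They ran from -1.01 for Ccdc160 to 1.46 for Gpc4, and dimmer neighbours were passed over. For these genes, this argues against loss of a wider stretch of the X chromosome. ES lines lacking Hprt are in wide use, so another ES line on the ESC arrays is a candidate explanation. Of 252 genes at least 2-fold from ESC in pNSC_L and pNSC_LF, 96 (38.1%) were also so in dNSC, against 15.3 for independent lists and at most 37 in 20 simulations that shared the ESC arrays and dealt out the dNSC changes to genes at random. These figures do not favour another line, since every later stage differs from ESC in culture too and a lasting effect of culture would leave the same overlap.

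Of the 20 naive pluripotency genes called higher in dNSC than in CNS_NSC, 17 had a dNSC mean at or above the median gene, which argues against a background of dim probe sets. The share of the pNSC_LF level kept in dNSC above CNS_NSC was computed on the linear scale. It covered 21 genes at least 2 log2 units higher in pNSC_LF than in CNS_NSC. It had a median of 13.4% and lay below 15% for 12 of them, from -1.5% for Klf4 to 78.3% for Sall4 and 167.8% for Lin28a, the only 2 above 50%. Zfp42, Tbx3 and Tfcp2l1, described above as genes of the naive state, kept 5.3%, 3.9% and 7.8%, against 25.9% for Pou5f1 and 26.4% for Nanog. The upper quartile of the share was 3.57 times the lower. Unchanged pNSC_LF cells as the whole source would give every gene a like share only if probe sets responded alike. That was not tested, and RMA compresses dim differences, so the quartile ratio does not decide this. Lin28a, higher in dNSC than in pNSC_LF, cannot owe its level to such cells alone. A primed-like state in these cultures is a hypothesis that needs primed epiblast genes to be higher in dNSC than in both other groups, as 11 of 18 were, but the overlap adds nothing to the 2 separate counts (10.9 for independent lists) and 5 of the 11 stand on other lists as well. The hypothesis stays open, as do neural regional identity, strain and origin, which were not tested.

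Dcn, Ccl2 and, chosen after its values were seen, Postn were higher in pNSC_L than in ESC, with Dcn at 8.79 and 10.41 on the pNSC_L arrays, and the whole feeder fibroblast list rose (9 of 25 genes higher and 2 lower, adjusted p = 7.5e-04, or adjusted p = 0.22 with an estimated correlation). Without pNSC_L replicate 2 the Dcn difference was 2.52 and still called, so that 1 array does not account for it. Fibroblasts carried over from the feeders would bring their abundant transcripts, yet 4 collagens and Sparc had a median difference of 0.30. This argues against more feeder cells in pNSC_L as the whole source. ESC were grown on feeders too, however, and their baseline may hold such RNA. Dcn read 6.06 and 6.48 in ESC, with a mean of 6.27 that lay under the lower quartile of probe sets. The genes and the rule of the collagen test were changed once after the values were seen and then put back to the first plan. Its outcome depends on them. With Fn1, Col5a1 and Col6a2 added, a demand that each gene lie under 1 by 2 SE left it undecided, since Fn1 reached 1.03. Each of Dcn, Postn and Ccl2 read lower in pNSC_LF than in pNSC_L and higher again in dNSC, but of the falls only that of Dcn was called. The Dcn call was lost without either pNSC_LF replicate and in further settings given above. Postn read 5.95 and 5.75 in pNSC_LF, under the lower quartile of probe sets. Dcn read 7.29 and 7.24 in pNSC_LF and 9.54 and 9.54 in dNSC, where Postn read 7.81 and 7.65 and Ccl2 8.57 and 8.595. The feeder fibroblast list also rose from pNSC_LF to dNSC, with 13 of 25 genes higher and 1 lower. Mitotically inactive feeder cells do not multiply on passage. The rise therefore argues against carried-over feeders as the source of these transcripts in dNSC. Whether the sphere cells of pNSC_L themselves make these transcripts stays open, and no biological explanation other than carried-over feeder cells was tested.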
